A study of Mus musculus with 30 samples.

How the data were processed

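The series holds 30 dual-channel microarrays made from mammary carcinomas of mice that carry a Myc transgene. Per the labels, 15 RNA extracts were each hybridised on 2 arrays, once in channel 1 and once in channel 2, against 1 reference RNA that is common to all arrays. What the reference was made from is not given in the sources used here. An extract code holds a number and a letter: 10 numbers occur, number 579 stands on 5 extracts, number 546 on 2, and the others on 1 each. What the number and the letter mark is not given, and the labels do not say whether extracts came from separate animals, so p-values measure only the spread between these extracts, which may be partly technical. Per the labels, 25 arrays belong to work on the change from epithelial to mesenchymal cells and 5 to work on tumour progression. Extracts 550-A and 561-B carry the second description on both arrays, and 595-A carries one description on each array.

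The deposited table gives log2 ratios of the 2 channels of each array for 22800 probes. That scale was read from the values, since background correction, normalization, filters and scanner are not given in the sources used here. Measured values ran from -9.86 to 11.83, and 33.6% of them equalled, at 3 decimals, the log2 of a ratio of whole numbers up to 20, where evenly spread values would give 2.95%. Such ratios could come from dim spots with few units of signal in both channels, or from rounding; channel intensities were not used here, and the cause was not tested. One value, 16.61 (log2 of 100000), occurred 8839 times with no other value above 11.83; it was taken as a placeholder and treated as missing, together with 95268 blank cells. This left 84.8% of the table, from 13434 to 21991 values per array. Probes rich in such ratios are called dim below.

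The deposited arrays were not centred on a common value. With the extract in channel 1 the array medians as deposited were 0.085 for 540-B, -0.189 for 546-A, 0.0255 for 546-B, -0.263 for 547-A, -0.396 for 548-A, -0.262 for 550-A, 0.415 for 561-B, 0.06 for 567-B, -0.175 for 579-A, -0.14 for 579-B, -0.941 for 579-D, -0.596 for 579-E, -0.844 for 579-F, -0.093 for 595-A and -0.554 for 597-B. In the same order, with the extract in channel 2, they were -0.131, -0.459, -0.585, -0.349, 0.041, 0.126, -0.518, -0.062, -0.435, -0.051, -0.387, -0.8895, -1.135, -0.857 and -1.00. The log scale is clear from the values, centring by the authors is absent between arrays, and the direction of the ratio stays unknown because the labels name no dye and no numerator.

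The paired arrays of an extract correlated below 0 over probes in all 15 extracts as deposited, with r from -0.556 (567-B) to -0.0087 (579-F). Arrays of different extracts correlated at a median r of 0.612 where the extracts were in channel 1 (lowest 0.287), 0.646 in channel 2 (lowest 0.346) and -0.229 in opposite channels. All arrays therefore ran the same channel over the other, and those of one orientation were turned. Arrays with the extract in channel 1 kept the deposited sign and those with it in channel 2 were turned. The Myc probe was then positive: "Myc side" below means the side on which Myc lay, and "opposite side" the other. Hints fixed before the data were examined disagreed, since skew over extracts was positive for 9 of 12 skeletal muscle genes (median 0.941) and for 2 of 12 milk genes (median -0.43). From the design, carcinomas of mice with a Myc transgene, the Myc side is likely the one on which the extract exceeded the reference; this basis is not proof, and values are given by side.

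Probes entered the tests with values on at least 24 of the 30 arrays and on at least 1 array of every extract, which kept 12888 probes; 6801 of all probes had values on every array. Of the kept probes, 6087 rested on 1 array in at least 1 extract, most often in 546-A (4021) and 548-A (3000), where the dye effect of a probe does not cancel. The probe annotation listed 17008 probes: 16874 with 1 symbol, 134 with several, which were not named, and 5792 further probes of the table were unlisted and stay unnamed here. By gene identifier 16196 of the single-symbol probes were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Of the kept probes 10750 had 1 symbol, for 9919 genes. No coordinates are given, because the build behind the probes is not given in the sources used here.

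Values of the paired arrays were averaged to 1 value per extract. The comparison with the reference tested these 15 means against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3; the reference is 1 RNA, so its own spread is left out. Differences between extracts were tested with limma's F-test on the 30 single arrays with a dye term for each probe; its error is the difference between paired arrays of 1 RNA, so it asks whether extracts differ by more than array noise. Number 579 (5 extracts) was set against the other numbers (10 extracts), and the 2 extracts described under tumour progression against 12 described under the change of cell state, both with limma; 595-A was left out of the latter. All tests were two-sided at a Benjamini-Hochberg adjusted p of 0.05 unless said otherwise.

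Gene lists were fixed before the data were examined, for 21 groups: epithelial, mesenchymal, fibroblast and matrix, basal and myoepithelial, milk and alveolar, hormone-sensing luminal, cell cycle, Myc target and nucleolar, ribosomal protein, lymphocyte, macrophage and myeloid, MHC class II, interferon response, adipocyte, skeletal muscle, endothelial, erythroid, hypoxia and glycolysis, squamous and keratinizing, immediate early and heat shock, and MAPK output. List counts use 1 value per gene, the mean of its probes. Shifts of lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. A list mean is the mean over member genes of the log2 ratio centred on each gene. Correlations of list means over extracts used 100000 permutations, and random lists of the same size were drawn 10000 times. Similarity of extracts that share a number was the mean r over probes of such pairs minus that of the other pairs, after each probe was centred on its mean over extracts. It was tested one-sided by 100000 permutations of the numbers. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the figures.

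Genes were named by a rule fixed before the data were examined, with 1 probe per gene, the single-symbol probe with the largest absolute moderated statistic in that comparison. Against the reference the rule took the 12 genes on each side with the largest mean among those past the threshold and on one side in all 15 extracts. Between extracts it took the 24 genes past the threshold with the largest SD. For number 579 and for the descriptions it took the 5 genes with the smallest p where fewer than 5 passed. It also took up to 4 members of each list with the largest statistic and a set of fixed genes, of which 15 were measured; the others are not reported here. Members on the smaller side of a list, other members named for single extracts, and probes named for sharing values were chosen after their values were seen.

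Array serial numbers in the labels fell into 6 runs with gaps of at most 10 within a run; these served as a stand-in for batches. Correlations were given only over 6 or more extracts. Each run held fewer, so none is given within a run, and the run was used as a fixed term instead.

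Each step was tested on simulated data built with the real missing values and spreads, with 200 of 12888 probes shifted. The simulated probes were independent and carried no dye effect, so false calls from dye effects or correlated probes were not measured. Against the reference 77.0% of probes shifted by 1 log2 unit were recovered with 7 other calls, and 96.5% at 2 units with 11. For number 579, 70.5% were recovered at 2 units with 13 other calls and 97.5% at 4 units with 11. For the descriptions the shares were 50.0% at 2 units with 6 other calls and 89.5% at 4 units with 16. Between extracts 44.0% were recovered at an SD of 1 with 7 other calls, and 88.0% at an SD of 2 with 14. In the camera step, run on 9919 genes and 21 lists, the 1 planted list was found and 0 others were called. The correlation steps recovered the planted relations and called 0 lists where none was planted. Genes were simulated as independent, while the correlation estimated from the data was 0.72 for ribosomal protein and 0.66 for fibroblast genes. The 0 other calls of both steps therefore say nothing about false calls from correlated genes.

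Alternatives fixed beforehand were subtraction of array medians, scaling to one spread, probes measured on all arrays only, single arrays with a dye term and the extract as a random block, no dye term, eBayes with trend and robust fitting, arrays of 1 orientation only, 1 mean per number or the number as a random block, the most variable probe of a gene, list genes past the between-extract test only, only the most variable probes, 595-A placed with either description, and each extract left out in turn. Added after seeing the data were a filter on dim probes (those with over 20% of values at small whole-number ratios left out, 7352 kept), groups of extracts left out together, the serial run as a fixed term, medians subtracted on fully measured probes, pairs of extracts without a shared serial run, 1 extract left out between extracts, and for the list shifts the estimated correlation, centring, scaling and fully measured probes; the test with the estimated correlation itself was part of the fixed tests.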

Results

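Expression was profiled in 15 RNA extracts from mammary carcinomas of mice with a Myc transgene, Myc being a transcription factor that drives cell growth and ribosome production. Each extract was set against 1 common reference RNA on 2 arrays with the channels exchanged. Arrays held from 13434 to 21991 measured probes, and 546-A and 548-A were the thinnest extracts. Values are log2 ratios to the reference, positive on the Myc side and negative on the opposite side, because the labels do not settle which channel was divided by which. High and low below mean toward the Myc side and away from it, and would change places if the ratio were turned.

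The comparison with the reference asked what sets these carcinomas apart from it. Trf, which encodes the iron carrier transferrin, lay farthest on the Myc side, at 7.93 ± 0.28 (SE, n = 15 extracts), a 243-fold difference. Genes of secretory mammary epithelium came next, among them the kappa-casein gene Csn3 at 6.29 ± 0.41, the siderophore-binding Lcn2 at 5.93 ± 0.21 and Elf5, the transcription factor of alveolar cells, at 4.92 ± 0.31. The lipid carrier Apoe stood at 5.21 ± 0.19, the tight junction gene Cldn3 at 4.76 ± 0.21 and the epithelial transcription factor Ehf at 4.70 ± 0.23. Gdpd3 (4.34), Tfr2 (4.17), Ceacam1 (4.07), Lrg1 (4.01) and 2610528J11Rik (3.81) completed the 12 largest on that side. Myc itself stood at 3.16 ± 0.11, an 8.95-fold difference, in all 15 extracts on one side, which was named after it.

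On the opposite side the farthest probes carried immunoglobulin names, led by Igkv4-57-1 at -7.08 ± 0.23 and Igkv6-14 at -6.73 ± 0.29, with Igkv4-70 (-6.17), Igkv4-68 (-6.00), Ighv6-6 (-5.73) and Igh (-5.68) behind them. They did not stand for all such probes: of 37 measured probes with heavy or light chain names, 14 lay on the opposite side and 4 on the Myc side past the threshold, with a median of -0.24. Hmga2, a chromatin protein of embryonic and mesenchymal cells, stood at -4.39 ± 0.34, and S100a4, a calcium-binding protein of fibroblasts, at -4.27 ± 0.20. Probes annotated to Ppp2r3c (-6.62), Scel (-4.29), Tuba4a (-4.23) and Rarb (-4.09) were also among the 12. Of 12 probes annotated to Ppp2r3c 11 lay on the opposite side and 1 on the Myc side. They ran from -6.62 to 0.89 with a median of -1.90, so the value printed is the extreme of probes that did not agree. The names Scel, Tuba4a and Rarb are uncertain too. The Scel and Tuba4a probes gave nearly one set of values, and only 1 of 2 Rarb probes lay on the opposite side.

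Epithelial genes lay on the Myc side and several mesenchymal ones on the opposite side. Epcam, an epithelial adhesion protein, stood at 2.90 ± 0.10, Cdh1 (E-cadherin) at 2.56 ± 0.33, and the luminal keratin genes Krt8 and Krt18 at 2.25 ± 0.15 and 0.83 ± 0.09, each on the Myc side in 15 of 15 extracts. The basal keratin gene Krt5 stood at 1.52 ± 0.28 and was on the Myc side in 13 of 15. Vim (vimentin) stood at -3.22 ± 0.22, Cdh2 (N-cadherin) at -2.34 ± 0.26 and the matrix gene Fn1 at -1.51 ± 0.19, and among the transcription factors that repress E-cadherin Zeb1 stood at -2.55 ± 0.23 and Snai2 at -1.40 ± 0.17. Twist1 was at -0.70 ± 0.20 (11 of 15 extracts on the opposite side) and turned side on arrays with the extract in channel 2. Snai1, at -0.46 ± 0.23 (adjusted p = 0.114), and the proliferation gene Mki67, at -0.18 ± 0.11 (adjusted p = 0.188), did not pass. After array medians were subtracted both passed on the opposite side, Snai1 at -0.55 (limma adjusted p = 0.0476) and Mki67 at -0.27 (0.049).

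In all, 6088 of 12888 probes differed from the reference by limma at an adjusted p under 0.05, 3912 on the Myc side and 2176 on the opposite side, and 1293 genes that passed lay on one side in all 15 extracts (916 and 377). The split depended on the level of the arrays: 64.3% of the calls were on the Myc side as deposited and 54.5% (3310 against 2763) after array medians were subtracted, while single orientations gave 43.2% and 76.0%. All 24 of the largest genes kept their side in both orientations. They were picked for large means over both orientations, on one side in every extract, which nearly fixed this outcome. The median over all genes was 0.16 as deposited and 0.07 after subtraction.

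Epithelial genes lay largely on the Myc side. Of 23 measured members 21 lay on the Myc side and 2 did not pass, with 21 adjusted over the list alone as well, a median of 2.10, and members such as Spint2 (2.95 ± 0.12), a protease inhibitor of epithelia, and Esrp2 (2.93 ± 0.15), a splicing factor of epithelial cells. Its shift passed camera at an adjusted p = 7.09e-10, and adjusted p = 0.0223 with an estimated correlation, the only list of 21 to keep its call that way. Of 12 milk and alveolar genes 11 lay on the Myc side and 1 did not pass (11 adjusted over the list alone), with a median of 1.97. The adjusted p was 5.32e-05, and adjusted p = 0.236 with an estimated correlation. The beta-casein gene Csn2 averaged 5.17 ± 0.76 and Folr1 1.17 ± 0.16. Hormone-sensing luminal genes passed rarely: of 7, the luminal transcription factor gene Gata3 (0.89 ± 0.21) lay on the Myc side and 6 did not pass (1 adjusted over the list alone), with a median of 0.08 that turned to -0.04 after array medians were subtracted (adjusted p = 0.866). Tff3 then passed on the opposite side, at -0.25. Without that subtraction Tff3 turned side, to 0.36, on arrays with the extract in channel 2. Of 9 basal and myoepithelial genes 3 lay on the Myc side, the integrin genes Itgb4 (2.17 ± 0.27) and Itga6 (1.05 ± 0.14) and Krt5, while Acta2, the smooth muscle actin gene, stood at -1.85 ± 0.22 and 5 did not pass (4 adjusted over the list alone; adjusted p = 0.869). Among 10 squamous and keratinizing genes Tgm1 (0.86 ± 0.23), Lor and Ivl lay on the Myc side, Sprr1a (-0.64 ± 0.15) on the opposite side and 6 did not pass, with 3 adjusted over the list alone (adjusted p = 0.866). Lor and Ivl no longer passed after array medians were subtracted.

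Mesenchymal genes lay mostly on the opposite side, 22 of 28 measured, with 2 on the Myc side and 4 not passing (24 adjusted over the list alone) and a median of -0.98. Prrx1, a transcription factor of mesenchyme, stood at -3.16 ± 0.27 and Lox, which crosslinks collagen, at -3.45 ± 0.30, while Pmp22 (0.70) and Tgfb3 (0.51) were the members on the Myc side. Camera gave an adjusted p = 5.11e-11, and adjusted p = 0.252 with an estimated correlation. Fibroblast and matrix genes followed, with 12 of 20 on the opposite side, Postn (2.18 ± 0.35), which encodes the matrix protein periostin, on the Myc side and 7 not passing (13 adjusted over the list alone). Pcolce stood at -2.37 ± 0.21 and the proteoglycan gene Dcn at -1.96 ± 0.30. The median was -0.94, the adjusted p 7.02e-05, and adjusted p = 0.527 with an estimated correlation.

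Genes of the Myc programme lay on the Myc side by about 0.88 at the median. Of 27 Myc target and nucleolar genes 23 were on that side and 4 did not pass (25 adjusted over the list alone), led by the translation factor gene Eif5a (1.31 ± 0.08), the transferrin receptor gene Tfrc (1.81 ± 0.16) and the nucleolar genes Nop56 (1.01 ± 0.10) and Fbl (0.88 ± 0.08). The adjusted p was 1.38e-06, and adjusted p = 0.3 with an estimated correlation. After array medians were subtracted 21 were on the Myc side and 1 on the opposite side. Of 35 ribosomal protein genes 20 lay on the Myc side, 2 on the opposite side (Rpl32 at -1.71 ± 0.15 and Rplp1 at -1.12 ± 0.13) and 13 did not pass, with 24 adjusted over the list alone, a median of 0.34 and an adjusted p = 0.119. After subtraction 13 lay on the Myc side and 3 on the opposite side. Cell cycle genes did not move with them: of 28, 7 lay on the opposite side, among them Bub1 (-0.95 ± 0.16) and Top2a (-0.83 ± 0.14), the replication helicase gene Mcm7 (1.01 ± 0.11) lay on the Myc side and 20 did not pass, with 8 adjusted over the list alone (adjusted p = 0.0609) and 11 on the opposite side after array medians were subtracted.

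Markers of other cell types of a tumour were mixed. Macrophage and myeloid genes lay on the Myc side for 10 of 16, such as the complement genes C1qc (2.91 ± 0.23) and C1qa (1.66 ± 0.13) and the lysozyme gene Lyz2 (3.27 ± 0.20), and on the opposite side for 3, Ptprc (-2.40 ± 0.16), Msr1 and Fcer1g, with 13 adjusted over the list alone (adjusted p = 0.207). All 9 endothelial genes lay on the Myc side (9 adjusted over the list alone), such as Sox18 (1.89 ± 0.26) and Cdh5 (1.56 ± 0.29), with an adjusted p = 0.00376, and adjusted p = 0.236 with an estimated correlation. Of 11 lymphocyte genes 3 lay on the opposite side, Ms4a1 (-1.39 ± 0.12), Cd28 (-1.27 ± 0.23) and Cd3g (-0.61 ± 0.16), and 8 did not pass (3 adjusted over the list alone; adjusted p = 0.108). Both MHC class II genes that passed, H2-Aa (2.57 ± 0.32) and H2-Ab1 (1.50 ± 0.33), lay on the Myc side, and Cd74 did not pass (2 of 3 adjusted over the list alone; adjusted p = 0.269). Of 15 adipocyte genes 7 lay on the Myc side, including Ucp1 (2.30 ± 0.13) and Fabp4 (2.06 ± 0.39), and Cd36 on the opposite side, with 10 adjusted over the list alone (adjusted p = 0.203). Hba-a1, an alpha-globin gene, stood at 2.84 ± 0.17 and the other 2 erythroid genes did not pass (1 adjusted over the list alone; adjusted p = 0.395). Of 12 skeletal muscle genes only Eno3 passed over all genes, at -0.63 ± 0.19, with 0 adjusted over the list alone (adjusted p = 0.587). Eno3 turned side, to 0.16, on arrays with the extract in channel 2.

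Of the stress and signalling lists, those of hypoxia and of immediate early genes passed camera at the preset correlation, toward the opposite side, and neither passed with an estimated one. Of 14 hypoxia and glycolysis genes 8 lay there and 1, Ddit4, on the Myc side (9 adjusted over the list alone), with the collagen hydroxylase genes P4ha1 (-3.02 ± 0.19) and P4ha2 (-2.15 ± 0.17) and the mitophagy gene Bnip3 (-2.17 ± 0.24) in front, a median of -0.70, an adjusted p = 7.02e-05 and adjusted p = 0.236 with an estimated correlation. Of 15 immediate early and heat shock genes 8 lay on the opposite side and 1, Hspa1a (1.08 ± 0.17), on the Myc side (9 adjusted over the list alone). The 8 include Hspa8, for which 1 of 2 probes lay on that side and may read another RNA. Dusp1 stood at -2.13 ± 0.23 and Egr1 at -1.75 ± 0.18. The adjusted p was 0.000909, and adjusted p = 0.236 with an estimated correlation. Of 10 MAPK output genes 3 lay on the opposite side, the growth factor gene Ereg (-2.53 ± 0.30), Fosl1 (-1.77 ± 0.16) and Ccnd1 (-0.68 ± 0.20), and Phlda1 (2.19 ± 0.28) on the Myc side, with 4 adjusted over the list alone (adjusted p = 0.108). Interferon response genes split, with Gbp2 (1.24 ± 0.39) and Psmb8 (0.84 ± 0.27) on the Myc side, B2m (-0.73 ± 0.29) on the opposite side, 15 of 18 not passing and 0 adjusted over the list alone. After array medians were subtracted 1 lay on each side. Its median was 0.21, while camera, which compares the list's moderated statistics with those of other genes, placed it lower than those (adjusted p = 0.866).

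**Figure D1:**
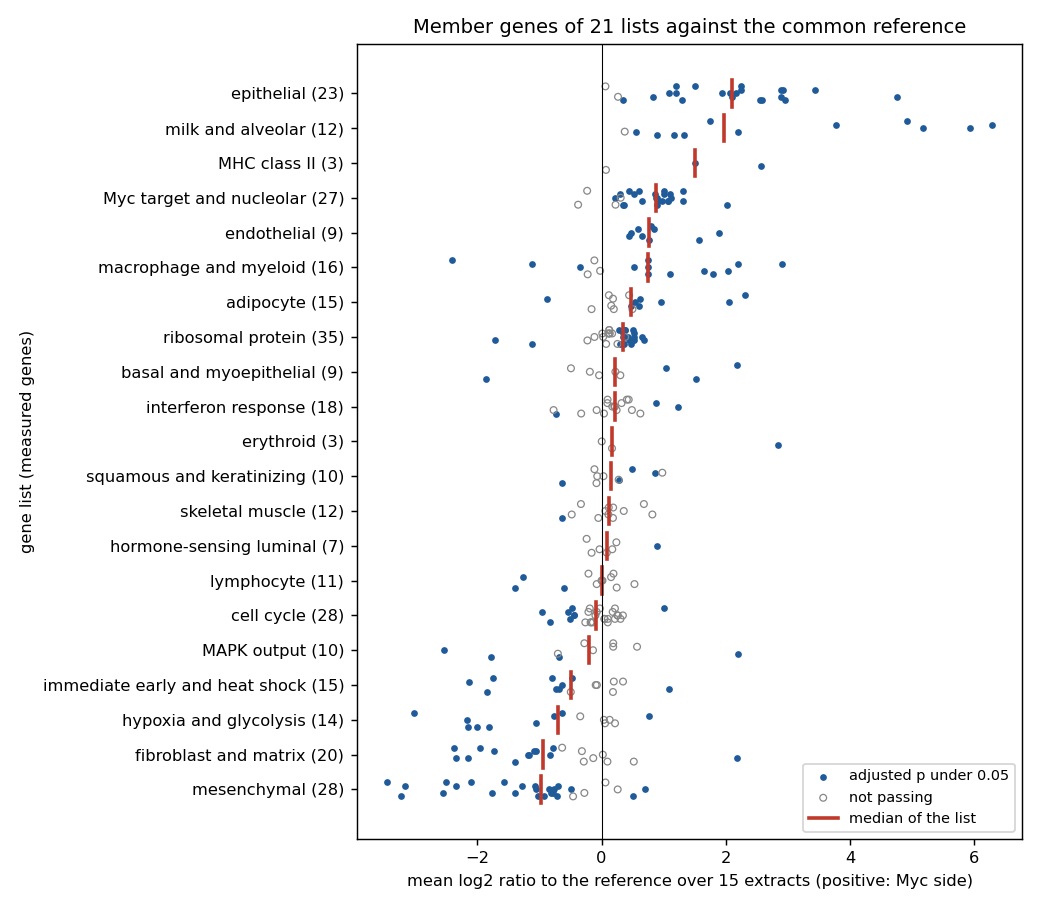
Mean log2 ratio to the reference (horizontal axis, positive on the Myc side) of each measured gene in the 21 lists, over 15 extracts; filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians. Epithelial and milk genes sit on the Myc side with medians of 2.10 and 1.97, and mesenchymal and fibroblast genes on the opposite side with medians of -0.98 and -0.94.

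The next comparison asked which genes differed between the carcinoma extracts by more than array noise. Csn2 ranged from -0.04 in 550-A to 9.29 in 547-A (SD 3.25 over 15 extracts), and the acute phase gene Saa1 from -1.71 in 548-A to 7.80 in 579-A (SD 3.48). Fgfr2, a receptor for fibroblast growth factors, stood at 7.13 in 548-A, 5.93 in 579-D and 6.99 in 597-B and at 0.91 or less in every other extract. Car6, a secreted carbonic anhydrase, and Dio1, a thyroid hormone deiodinase, were high in the same extracts: in 540-B, 546-B, 548-A, 561-B, 579-D, 579-E, 579-F and 597-B Car6 lay between 4.11 and 8.11 and Dio1 between 3.64 and 7.27, while in the rest Car6 lay at 1.75 or less and Dio1 at 0.73 or less. The extracts of number 579 stood on both sides of this gap.

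Further genes of large SD peaked in other extracts. The milk mucin gene Glycam1 reached 7.98 in 595-A, Ltf (lactoferrin) 7.41 in 579-E and 7.06 in 561-B, Mucl2 8.41 in 579-E, and Scgb1b27 6.80 in 579-D. The matrix gene Tnc stood at 4.53 in 546-A and 4.35 in 550-A against -3.53 in 579-D, and the muscle actin gene Acta1 at 5.92 in 546-A and 4.27 in 546-B against 2.13 or less elsewhere. Interferon-inducible GTPase genes were high in 546-A, with Tgtp1 at 8.36 and Igtp at 5.09, each on 1 array, in 579-D, with 3.48 and 5.33, and in 597-B, with 2.85 and 3.46. Both also lay between 1.76 and 2.09 in 548-A and 567-B. Krt6b, a keratin of wounded epidermis, stood at 10.24 in 546-A, on 1 array, and 5.96 in 550-A. Borcs5, Pcdha6, Ecel1, Neb, Emid1, Cyp2f2, Prl2c3, Epb41l4a, Scel and Tuba4a completed the 24 genes of largest SD.

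**Figure D2:**
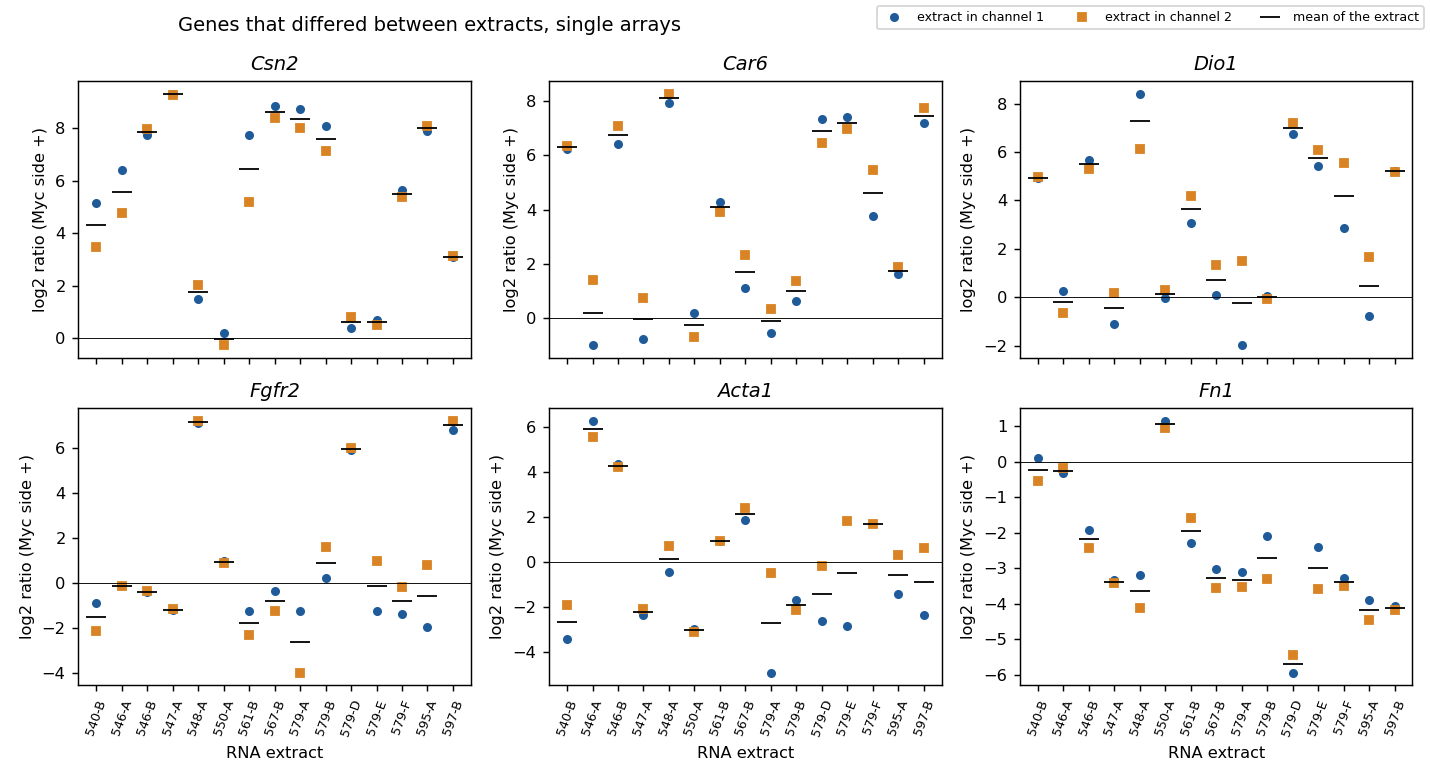
Log2 ratio to the reference (vertical axis, positive on the Myc side) of 6 genes in each of 15 extracts; circles and squares are the array with the extract in channel 1 and in channel 2, and bars their mean. Fgfr2 is high in 548-A, 579-D and 597-B on both arrays, and Acta1 in 546-A and 546-B.

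By limma's F-test 867 of 12888 probes differed between extracts, and at gene level 768 of 9919 genes (7.74%). Interferon response genes differed most often, 13 of 18 (72.2%), followed by MHC class II (2 of 3), fibroblast and matrix (13 of 20, 65.0%), hypoxia and glycolysis (9 of 14), MAPK output (6 of 10), immediate early and heat shock (7 of 15), mesenchymal (12 of 28) and milk genes (5 of 12). Epithelial genes differed for 5 of 23, among them Krt7 (SD 1.49) and Krt19 (SD 1.40), macrophage genes for 3 of 16 and cell cycle genes for 2 of 28. The Myc target, ribosomal protein, basal, hormone-sensing, squamous and muscle lists each held 1 such gene, and the lymphocyte, adipocyte, endothelial and erythroid lists 0 by the same test. Among fixed genes Csn2, Fn1 (adjusted p = 1.95e-06), Vim (0.000438) and Krt8 (0.00357) differed, while Myc (SD 0.37, adjusted p = 0.57), Cdh1 (SD 1.43, 0.12), Zeb1 (0.149) and Mki67 (0.61) did not pass. After array medians were subtracted Krt8 no longer passed (adjusted p = 0.112) and Zeb1 did (0.0216). The count fell to 393 without a dye term and to 472 without 546-A and 548-A, the extracts with the fewest values.

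As list means, fibroblast and matrix genes ran from 1.87 in 546-A to -1.78 in 579-D (SD 1.07), and paired arrays ranked extracts alike (r = 0.96 over 15 extracts). MHC class II ran from 2.36 in 540-B to -1.79 in 595-A (SD 1.39, 3 genes), interferon response from 2.54 in 546-A to -1.01 in 540-B (SD 1.00), milk and alveolar from 1.67 in 595-A to -1.50 in 548-A (SD 0.95), and mesenchymal from 1.59 in 546-A to -1.02 in 579-D (SD 0.73). Skeletal muscle genes peaked in 546-A (1.61) and 546-B (1.51). The epithelial list mean had an SD of 0.30, where 80.3% of random lists of its size had a smaller one, and its paired arrays did not rank extracts alike (r = -0.06). Each of these ranges counts extracts of unequal quality, since 4021 of the tested probes in 546-A and 3000 in 548-A rested on 1 array.

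**Figure D3:**
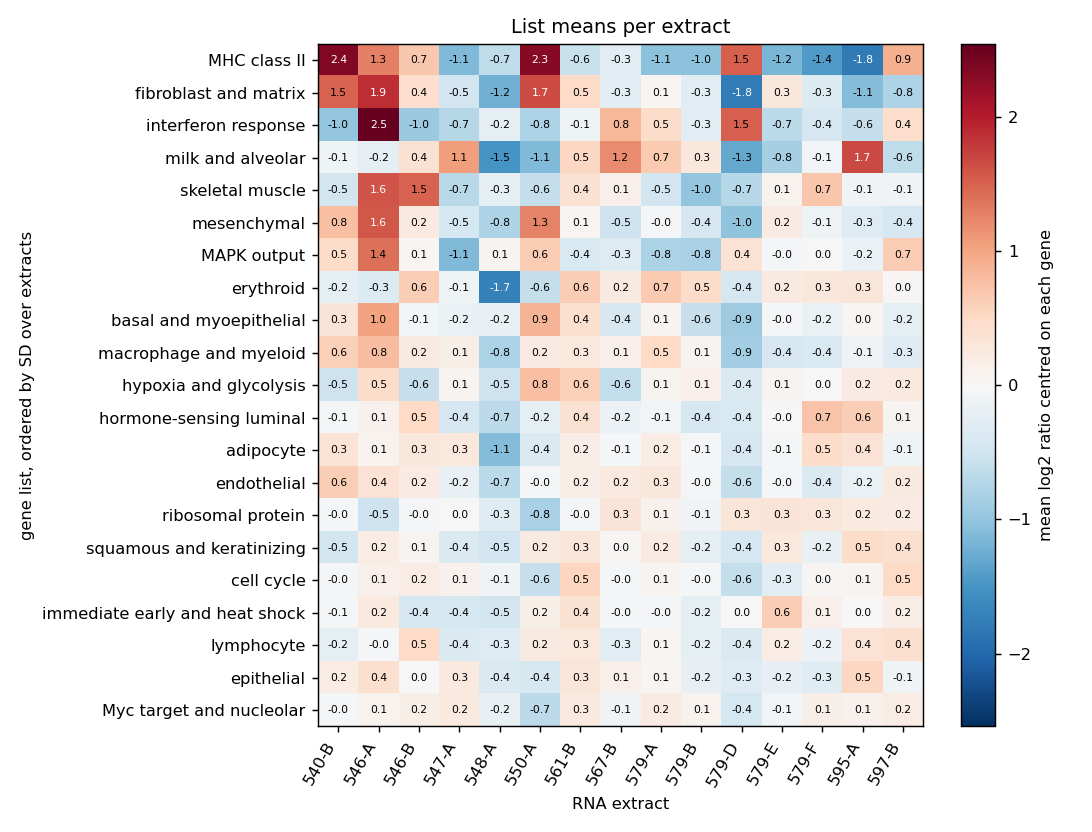
Mean log2 ratio of 21 gene lists (vertical axis, ordered by SD) in 15 extracts (horizontal axis), centred on each gene; red is toward the Myc side and blue toward the opposite side. Fibroblast and mesenchymal lists are highest in 546-A, 550-A and 540-B and lowest in 579-D.

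The submitters describe most arrays under a change from epithelial to mesenchymal cells, so list means were compared over extracts. Mesenchymal genes moved with fibroblast and matrix genes: 546-A, 550-A and 540-B, with mesenchymal means of 1.59, 1.26 and 0.76, had fibroblast means of 1.87, 1.66 and 1.51, and 579-D was lowest in both. Pearson's r was 0.953 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.0001 over 20 relations) and Spearman's rho 0.904 (p = 3e-05), with r = 0.937 without the 2 extracts farthest from the median, 0.946 after array medians were subtracted and 0.976 with the serial run as a fixed term. Because those 3 extracts stand apart, r was also computed over the other 12, where it was 0.897 (permutation p = 0.0001, adjusted p = 0.002). Within serial runs no value is given, since each holds fewer than the 6 extracts set as the least.

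Of the 20 lists 4 were correlated with the mesenchymal mean at an adjusted p under 0.05. Besides the fibroblast list these were basal and myoepithelial genes (r = 0.912, permutation p = 1e-05, adjusted p = 0.0001, rho = 0.868, p = 7e-05), macrophage and myeloid genes (r = 0.71, p = 0.00318, adjusted p = 0.0212, rho = 0.696, p = 0.00479) and, below 0, ribosomal protein genes (r = -0.664, p = 0.00859, adjusted p = 0.043, rho = -0.439, p = 0.104). Without the 2 farthest extracts, 546-A and 550-A, r was 0.779, 0.683 and -0.0933, so the ribosomal relation rests on those extracts. With the serial run as a term r was 0.906, 0.759 and -0.634. By permutation 8 lists then passed, with immediate early (r = 0.781), MAPK output (0.733), MHC class II (0.714) and endothelial genes (0.604) added. Those permutations did not count the terms fitted for the 6 runs. Their p-values are therefore too small, and the added lists are not established. With 1 mean per number 2 lists passed. For the macrophage list 98.1% of random lists of its size had a lower r, and 94.99% after array medians were subtracted. Over the 12 extracts that exclude 540-B as well, r was 0.734 (adjusted p = 0.0531) for the basal and 0.584 (adjusted p = 0.0778) for the macrophage list, and 1 list, the fibroblast one, stayed below 0.05. Paired arrays ranked extracts less alike for the basal list mean (r = 0.47) than for the mesenchymal one (r = 0.81). Only 1 of 9 basal genes differed between extracts by more than array noise, which limits what the basal relation can show.

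Epithelial and mesenchymal list means showed no opposite movement. Pearson's r over 15 extracts was 0.222 (permutation p = 0.427) and rho 0.221 (p = 0.427), with r = 0.341 (p = 0.254) without 546-A and 550-A. Pairs of random lists of the same sizes had a median r of 0.727 as deposited, and 0.59% of them lay below 0.222. Where the mesenchymal list was kept and only the epithelial one replaced by random lists, 44.2% lay below it. After array medians were subtracted, which takes out the offset shared by all genes of an array, r was 0.118 (p = 0.675), rho -0.161 (p = 0.567) and 41.6% of random pairs lay lower. With the serial run as a term r was 0.055 (p = 0.846). Restricted to list genes that differed between extracts, r was 0.69 (p = 0.00408), on 5 epithelial and 12 mesenchymal genes. The epithelial mean was not reproducible between paired arrays, which limits what this relation can show.

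**Figure D4:**
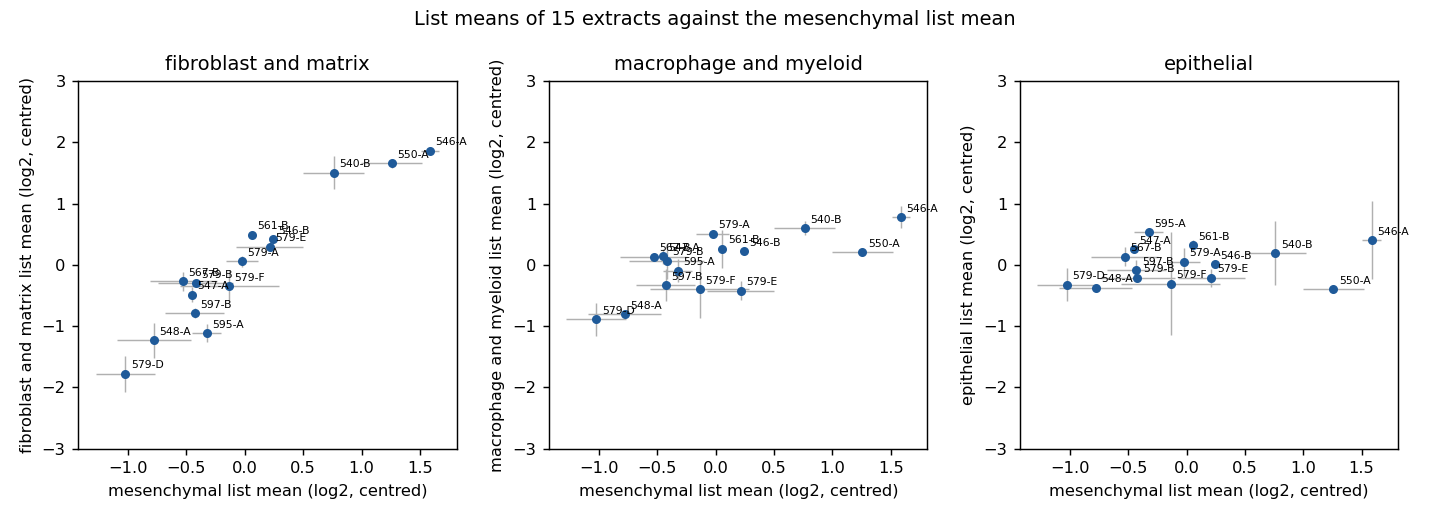
Fibroblast, macrophage and epithelial list means (vertical axes, log2, centred on each gene) against the mesenchymal list mean (horizontal axis) in 15 extracts; bars show the spread of the paired arrays. The fibroblast list follows the mesenchymal list (r = 0.953), and the epithelial list does not (r = 0.222).

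No excess resemblance was seen between extracts that share a number in their code. Each probe was first centred on its mean over extracts, which by itself pulls the r of pairs below 0. The mean r over probes was then -0.0732 for the 11 pairs with one number and -0.0646 for the 94 other pairs. The difference was -0.00858 (one-sided permutation p = 0.572). Among pairs with no serial run in common it was -0.0252 (p = 0.774, 8 and 77 pairs), and after array medians were subtracted -0.00491 (p = 0.522). Paired arrays of 1 RNA were often little alike themselves. As deviations from the mean of their orientation they correlated from -0.0335 (597-B) to 0.561 (579-D). A resemblance within a number could therefore have been missed. All pairs with one number except 546-A with 546-B were of number 579.

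Number 579, the only one with more than 2 extracts, differed from the others most in 4931406B18Rik (-1.78 ± 0.35 SE), Cdh1 (-2.29 ± 0.46), Trf (-2.08 ± 0.42), Col9a1 (-3.57 ± 0.74) and Slain1os (-1.08 ± 0.26), none of which passed limma (adjusted p 0.61 for the first 4 and 0.957 for the last). Cdh1 averaged 1.03 ± 0.41 (SD) in the 5 extracts of that number and 3.32 ± 1.04 in the other 10, and Trf 6.60 ± 0.50 and 8.68 ± 0.93. Myc differed by 0.50 ± 0.20 (limma adjusted p = 1.00). By limma 0 probes passed, 460 had an unadjusted p under 0.05, and each alternative fit gave 0 as well. Camera called 7 lists, among them ribosomal protein genes toward the Myc side (adjusted p = 1.37e-13) and, toward the opposite side, fibroblast and cell cycle genes (both 0.00474), mesenchymal (0.00664), macrophage (0.0327) and basal genes (0.0488), with interferon genes toward the Myc side (0.0488). With an estimated correlation 0 were left, at adjusted p = 0.638 with an estimated correlation for all but the mesenchymal (0.68) and interferon (0.729) lists. Over the list alone only the epithelial list held a member that passed, 1 of 23.

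The 2 extracts described under tumour progression, 550-A and 561-B, were set against the 12 described under a change of cell state. A single probe passed limma, 4930404H24Rik, at -2.90 against 0.36, a difference of -3.26 ± 0.46 (SE, adjusted p = 0.0405), measured on 26 arrays. Fbxl17 (1.88 ± 0.39), Fam184b (1.51 ± 0.31), Plpp6 (-1.84 ± 0.39) and Rhpn1 (1.74 ± 0.40) followed without passing (adjusted p 0.774, and 0.945 for Rhpn1), and 525 probes had an unadjusted p under 0.05. The call was lost, with 0 probes passing, after array medians were subtracted and when 595-A was placed with the progression extracts, and 1 RNA carried both descriptions.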

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

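Among the 5 extracts of number 579, the only group of 4 to 10 extracts, 7 of 63 items had 1 extract far from the other 4. The 5% rate of the outlier test would flag 3.2 of independent, unselected items. Part of the items were genes picked for a large SD over these same extracts, which favours outlying extracts, and items are not independent. The 3.2 is therefore not the number expected by chance here. The tests weighed for the patterns of this part and the count of other splits were chosen after the results were seen.

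In 579-D the MHC class II list mean stood at 1.52 against -1.43 to -1.04 in the other 4. The hypoxia and glycolysis list mean of 579-D was -0.36, against 0.01 to 0.14, but once array medians were subtracted it was 0.0067, within the -0.0434 to 0.275 of the other 4, so the gap does not hold. Fn1, by the probe that varied most between extracts, lay at -5.68 in 579-D and between -3.38 and -2.70 in the others. Pcdha6 lay at -5.57 in 579-D, against -2.70 to -1.70. In 579-E, Mucl2 stood at 8.41 against 1.00 to 1.88, and Ltf at 7.41 against 3.61 to 4.21. Mki67 lay at -0.84 in 579-E, against -0.28 to -0.08, but it did not differ between extracts by more than array noise (limma adjusted p = 0.61). No explanation of these single extracts was tested.

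The count of 0 probes for number 579 was set against other splits of the extracts into 5 and 10. With a real count of 0, all 100 splits drawn reach it by construction (highest of the others 1), so this count tells nothing about chance. At an unadjusted p under 0.05, where number 579 gave 460 probes, 62 of the 100 splits gave as many, so chance is not excluded there; the highest gave 1577, and whether a structure of the samples lies behind it was not tested.

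Mesenchymal and fibroblast list means moved together over the extracts. Offsets between whole arrays do not account for this, since r was 0.946 once array medians were subtracted, and the serial run of the arrays did not account for it, with r = 0.976 when it was a fixed term. A like rise in RNA of every stromal cell type was weighed by the slope of the macrophage on the fibroblast list mean. That slope was 0.332 (95% bootstrap interval 0.242 to 0.415). A shallow slope does not exclude such a rise, because the lists differ in how far their genes vary. Between extracts 13 of 20 fibroblast genes but 3 of 16 macrophage genes differed by more than array noise. A like rise, a different share of fibroblasts, and tumour cells that express matrix genes all stay open. Each could give the pattern, and fibroblasts express most of the mesenchymal list as well. None of them was tested further, because the labels give no group that separates 546-A, 550-A and 540-B from the rest.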

How the results depend on the processing

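Alternatives named as added in the processing summary (dim-probe filter, groups of extracts left out, serial run as a term, combined settings and those of the list shifts) were chosen after seeing the data. Against the reference, 26 of 27 alternatives gave between 4683 and 6477 probes (5756 to 6319 with each extract left out), and fully measured probes gave 4047 because fewer probes were tested. Between extracts, 7 of 9 gave 607 to 1248; no dye term gave 393, and leaving out 546-A and 548-A gave 472; the cause was not tested. Number 579 gave 0 under all 16. For the descriptions, 0 probes passed under array medians subtracted, scaling, fully measured probes, the extract as a random block, channel 1 only, channel 2 only, 595-A with progression, the dim-probe filter, and without 546-A and 548-A or 579-E and 579-F; leaving out 550-A or 561-B gave 3 and 4, the lone extract being assumed to vary like the others. Of 8 shifted lists 1 held with an estimated correlation, and other settings gave 7 to 9. Lists correlated with the mesenchymal mean numbered 4, with 7 on fully measured probes with medians subtracted, 8 in channel 1, 2 in channel 2, 2 with 1 mean per number, 8 with the serial run as a term, 1 without 540-B, 546-A and 550-A, and 2 to 6 with each extract left out, the 2 without 546-A. The 8 with the serial run rest on permutation p-values that are too small, since the run terms were not counted. The epithelial and mesenchymal correlation passed only on list genes that differ between extracts (0.690), and ranged from -0.0019 to 0.488 with each extract left out. The similarity of extracts with one number stayed without a call throughout (-0.0305 to 0.0079 with each left out). Where not named, the cause was not tested.

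Among named genes against the reference, 1170 values kept their call, 24 gained it, 16 lost it and 6 turned side, all 6 in single orientations: Twist1 0.20, Tff3 0.36, Foxa1 0.81 and Eno3 0.16 in channel 2, and Ccr7 -0.86 and Epb42 -0.82 in channel 1; the cause was not tested, and a dye effect does not cancel in 1 orientation. Between extracts 526 values kept their call, 27 gained and 33 lost it. No paired analysis was possible because the labels pair no extracts across groups. Signal over background was not used here; 33.6% of values were small whole-number ratios, whose cause was not tested.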

Other observations

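The weighing tests of this part were chosen after the results were seen; the lists were fixed before. Antigen presentation and interferon genes lay toward the Myc side together in some extracts and apart in others; with the ratio turned, every high value of this part would be a low one. In 579-D the interferon list mean was 1.51 and the MHC class II mean 1.52, with Psmb8, an immunoproteasome subunit gene, at 3.07 and B2m at 1.66. In 546-A the means were 2.54 and 1.29, with Tap1, a peptide transporter gene, at 2.43 and Irf1, on 1 array, at 1.81. In 540-B and 550-A the MHC class II means were 2.36 and 2.32 while the interferon means were -1.01 and -0.80, and Cd74, the invariant chain gene, stood at 2.47 and 2.93. In 567-B and 579-A, interferon means of 0.85 and 0.47 went with MHC class II means of -0.27 and -1.05.

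MAPK output genes ranged from 1.39 in 546-A to -1.13 in 547-A as a list mean (SD 0.65; r of paired arrays 0.78). Dusp6, a phosphatase gene induced by ERK signalling, ran from 1.48 in 546-A to -2.49 in 561-B, Etv5 from 2.80 in 546-A to -2.16 in 547-A, Ccnd1 (cyclin D1) from 1.47 in 550-A to -1.89 in 547-A, and Phlda1 from 4.07 in 579-D to -0.45 in 547-A. Hypoxia and glycolysis genes lay farthest to the Myc side in 550-A (0.76) and to the opposite side in 567-B (-0.63), or in 546-B (-0.80) after array medians were subtracted, with Egln3 at 0.63 in 546-A and -2.21 in 579-A.

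Skeletal muscle genes lay on the Myc side in 546-A and 546-B, with list means of 1.61 and 1.51. Acta1, Ckm, Mylpf, Tnnt3 and Des, 5 of 12 genes, lay farther to that side in both than in the 13 other extracts, and 1 of the 105 pairs of extracts had as many; since the pair was picked for these genes, this restates the pattern, and RNA of skeletal muscle is not decided by it. With the ratio turned, these 5 genes would be lowest in both extracts. The array serial run does not account for the pattern, since the list mean of its other 3 extracts was at most -0.25, while noise of single arrays stays open, since the lowest list mean of the arrays of 546-A and 546-B was 0.54 and the highest of the other arrays 1.26. Tnni2 adds to that spread, at -7.42 in 546-A and 4.09 in 546-B, each on 1 array and of opposite orientations, and no biological explanation from the design was tested.

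The probes annotated to Scel and Tuba4a gave nearly one set of values, with a median absolute difference of 0.15 over 15 extracts (largest 3.98). That the probes read an RNA other than the named genes is a candidate explanation: the other Tuba4a probe differed from this one by 5.95 at the median of 13 extracts. For the Scel probe paired arrays differed by 0.44 against an SD of 2.34 over extracts. The Tuba4a probe was noisier, with an array noise SD of 1.52 against an SD of 2.66 over extracts. Noise of single arrays would make the probes differ, so these values do not bear on why they agreed. Besides the Scel probe itself, 13 probes had an r above 0.8 with it over arrays, all with a mean on the opposite side: 9 unnamed and 4 annotated to 1600010M07Rik, Hspa8, Rarg and Sult6b1. The Tuba4a probe was not among them, and differed most from the Scel probe in 561-B. Which RNA they read was not tested, since probe sequences were not used here.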
